A study of Mus musculus with 33 samples.

How the data were processed

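The series held 33 mouse samples, all from animals at 3 weeks of age that were wild type (WT), heterozygous (Het) or homozygous null (KO) for Dnmt3a, which encodes a de novo DNA methyltransferase. RNA-seq was done on 12 of them. In 6 libraries the RNA came from mature olfactory sensory neurons (mOSN) isolated by fluorescence-activated sorting, with 2 libraries per genotype. In the other 6 it came from the whole main olfactory epithelium (MOE) of animals exposed for 60 min, after 10 min of habituation, to 80 µL of water or of an equal mixture of amyl acetate, acetophenone and octanal (odor below), with 1 library per genotype and treatment. The remaining 21 samples (immunoprecipitated methylated and hydroxymethylated DNA, histone marks, DNase and inputs) were not analysed here because no processed table of theirs was available. Per the labels, ribosomal RNA was depleted, both WT mOSN libraries were made with ScriptSeq from 200 ng, both KO mOSN libraries with NuGEN from 100 ng, and Het with 1 of each. All MOE libraries were made with NuGEN. Library kit and genotype are therefore confounded between WT and KO mOSN.

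Both tables hold values that the authors call RPKM (a read density by gene length and library depth). Per the submitters' processing notes the tools were Bowtie2 2.1, STAR 2.3.0, Picard 1.64, featureCounts and DESeq, with the genome builds mm9 and NCBIM37, and neither their order nor the normalization formula was stated. The deposited MOE table has 14613 genes and 1 column per library. Its values were checked to be whole reads times a library factor over a gene length: for all 14613 genes (100%) the ratios between libraries could be written as ratios of whole reads within a relative tolerance of 1e-05. The library factor followed a median-ratio size factor (their product ranged from 0.989 to 1.028 between libraries) more closely than total reads (0.944 to 1.058), and the columns did not share a common sum. The values are therefore called deposited RPKM-scale values, and absolute levels should not be read as strict RPKM. The recovered reads, exact up to a divisor that a gene's 6 counts share, came to 12472278 in WT water, 13495341 in WT odor, 13316758 in Het water, 17639584 in Het odor, 9410063 in KO water and 11384079 in KO odor. On simulated data the whole reads came back exactly for 98.2% of genes, and for 100% up to such a divisor. The deposited mOSN table has 14751 rows, of which 7 without values were left out, and 1 pooled value per genotype. How the 2 libraries of a genotype were combined is not stated, and their depth could not be recovered. Neither table held a value of 0, and whether genes at 0 in a column had been left out is not stated.

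Genes were matched by Ensembl identifier to reference gene names (14337 of the MOE and 14464 of the mOSN identifiers); coordinates were not used, as no annotation of the authors' build was available. Values were taken as log2 with a pseudocount of 0.5 after keeping genes at 0.5 or more in at least 2 columns, which left 14602 MOE and 14738 mOSN genes. MOE comparisons were fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p, threshold 0.05). Odor against water had genotype as a block, and genotypes were compared with treatment as a block, with 2 residual degrees of freedom. The odor effect in KO was tested against the common effect in WT and Het, with 1 residual degree of freedom, which assumes that WT and Het respond alike. Nothing in the labels says which libraries share animals, so p-values measure only the spread between these libraries. With 1 library per genotype and treatment, the error of the odor and genotype tests came from differences in odor effect between genotypes. A response to odor that depends on genotype thus counts as error in those tests. For the odor effect in KO, the error came from the difference between the WT and Het odor effects. No pairing of replicates applied. On data simulated from this design, 20% of 50 genes changed by a log2 of 1, 94% of 50 changed by 2 and 100% of 50 changed by 3 were called, with 17 unchanged genes called. The simulated noise was independent between genes, with gene variances pulled toward their median, while gene groups moved together between the real libraries. These shares are therefore not the power in the real data, and a comparison without calls does not show that nothing changed.

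The limma tests planned for mOSN could not be run because the table holds 1 value per genotype. The mOSN values are given as the authors' pooled values with no test, and genes at least 2-fold apart were counted instead. Gene lists were tested in MOE with limma's camera at a preset correlation of 0.01 (29 lists of at least 3 tested members per comparison, adjusted over the lists). Beside it stand camera with an estimated correlation, whose p rests on the fit's 2 or 1 residual degrees of freedom, and fry. In both tables a list's median was also ranked among 10000 random lists matched on expression; of 100 simulated random lists, 2 fell outside the central 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

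The lists were marker genes of the mature neuron, immature neuron, basal progenitor and dividing cell, horizontal basal cell, sustentacular cell, Bowman gland and secretory cell, ensheathing and Schwann cell, macrophage and leukocyte, erythroid cell, endothelial and mesenchymal cell and microvillous cell. The receptor families were odorant, trace amine-associated and vomeronasal receptors. The others were immediate early, olfactory activity-linked, heat shock, DNA methylation, Polycomb, Hox, other-lineage developmental transcription factor, germline, imprinted, clustered protocadherin, axon guidance, synaptic vesicle, oxidative phosphorylation and ribosomal protein genes, replication-dependent histones, mitochondrially encoded genes, non-polyadenylated RNAs and Y-linked genes. Mitochondrially encoded genes and non-polyadenylated RNAs had no member in either table, and Hox genes none in the MOE table.

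Genes were named by rule: Dnmt3a first, then per tested comparison the 10 largest changes in each direction among genes past the threshold with the same direction in every library difference. Where fewer than 5 passed, the list was filled to 5 by moderated t and each such gene is said not to pass. Predicted genes, receptors and small RNAs were left to group counts. Per list, 2 to 4 members with the smallest p (without a test, the highest value) were taken, along with Olfr2 and Olfr160, receptors known to bind octanal and acetophenone. Tests, lists, most alternatives and this rule were fixed before the data were examined. For mOSN, the 12 largest differences per direction with Het between WT and KO and a value of at least 50 in the higher genotype were named, a rule chosen after the table was seen. Het values between WT and KO in these named genes are thus a condition of the rule and not a result. Alternatives covered pseudocounts, filters, scaling (median-ratio, quantile), the trend, the threshold, blocks, voom on recovered reads and leaving out pairs or libraries.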

Results

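RNA was measured in sorted mature olfactory sensory neurons, the odor-detecting neurons of the nose, and in the whole main olfactory epithelium (MOE) that also holds their precursors and supporting cells. The mOSN table gave 1 pooled value for each of the 3 genotypes, from 2 libraries each. The MOE table gave 6 libraries, each of the 3 genotypes with water and with odor, without replicates. Recovered reads ranged from 9410063 in KO water to 17639584 in Het odor, with a median of 222 to 396 reads per gene. All values are deposited RPKM-scale values, and errors are standard errors of limma's log2 fold change.

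Dnmt3a (ENSMUSG00000020661), the targeted gene, was lower in both mutant genotypes and was still counted in KO. In mOSN its pooled value was 174.7 in WT, 119.9 in Het and 56.2 in KO, or 68.6% and 32.2% of WT. In MOE it was 84.4 with water and 89.0 with odor in WT, 50.3 and 66.6 in Het, and 56.1 and 48.3 in KO. The KO mean was 60.3% and the Het mean 67.4% of the WT mean, with a log2 fold change of -0.73 ± 0.24 for KO and -0.58 ± 0.24 for Het against WT. Neither passed limma's test (two-sided, adjusted p = 1 and 0.706). The labels do not say which part of the gene was removed, so reads over the rest of it can still count.

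Among other genes of DNA methylation, Dnmt1, the maintenance methyltransferase, was 289 in WT, 252 in Het and 226 in KO mOSN. Dnmt3b stayed under 2 in every mOSN column and MOE library. Tet3, which oxidizes methylated cytosine, was 178, 171 and 158 in WT, Het and KO mOSN. In MOE it was 167 and 244 in WT, 190.2 and 173 in KO, but 906 and 2235 in Het. Reads of Tet3 numbered 14142 and 43643 in the Het libraries and 2174 to 3597 in the other 4. Its log2 fold change of 2.82 ± 0.34 between Het and WT did not pass (adjusted p = 0.706).

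**Figure D1:**
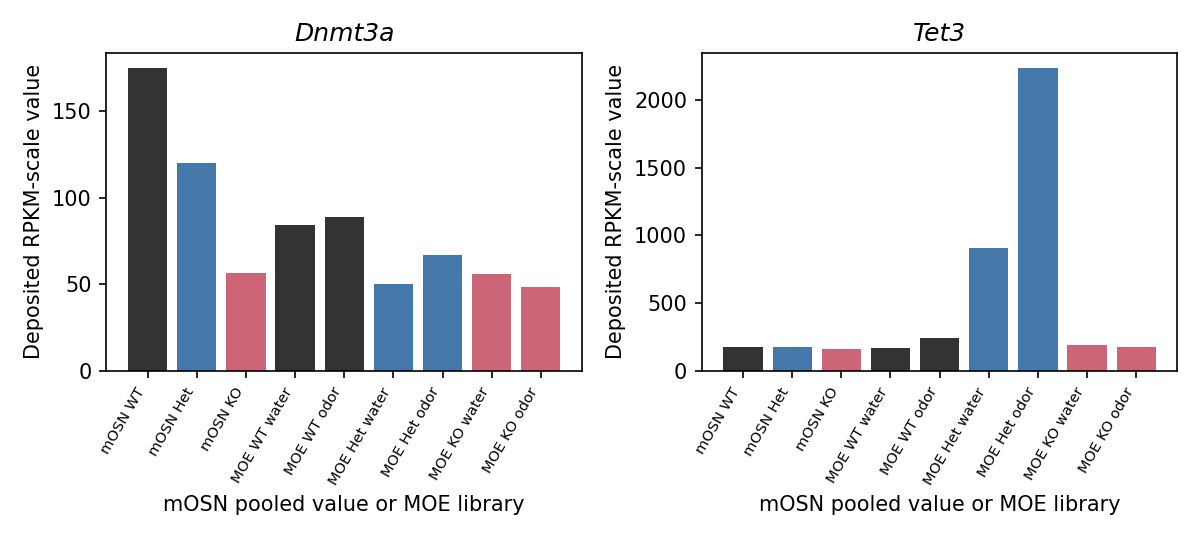
Deposited RPKM-scale values (vertical axes, linear from 0) of Dnmt3a and Tet3 in the 3 pooled mOSN columns and the 6 MOE libraries; each bar is 1 value. Dnmt3a is lower in Het and KO than in WT in both tables, and Tet3 reaches 906 and 2235 in the Het MOE libraries alone.

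The first MOE comparison asks what 60 min of odor changes across genotypes. Fos and Egr1, immediate early transcription factors of neuronal activity, rose in all 3 genotypes. Fos (ENSMUSG00000021250) went from 20.7 to 523 in WT, from 29.2 to 341 in Het and from 22.4 to 322 in KO, a log2 fold change of 3.99 ± 0.25 (limma adjusted p = 0.0454). Egr1 (ENSMUSG00000038418) went from 44.8 to 639, from 63 to 606 and from 27.8 to 399, a log2 fold change of 3.63 ± 0.18 (limma adjusted p = 0.0249). Fosb (4.49 ± 0.34), the antiproliferative gene Btg2 (1.9 ± 0.14) and the orphan nuclear receptor Nr4a1 (3.43 ± 0.35) came next and did not pass, with adjusted p = 0.0722, 0.0722 and 0.276. They passed with voom (adjusted p = 0.0089, 0.0257 and 0.0174), Fosb and Btg2 with a minimum of 100 reads (0.0201 and 0.0306), and Fosb and Nr4a1 without the WT pair (0.0442 for each). Of the 31 immediate early genes measured, 30 were higher and 1 lower, with a median log2 of 1.19; 2 passed over all genes and 22 adjusted over the list alone.

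Limma called 2 genes higher and 0 lower among 14602. At an unadjusted p under 0.05 there were 439 higher and 272 lower, and voom on the recovered reads called 6 higher and 0 lower among 14288. Both calls were lost without the Het pair (adjusted p = 0.214 for Fos and 0.0737 for Egr1), without the KO pair (0.167 and 0.117) and without the Het odor library (0.268 and 0.0896), where limma called 0 genes; without the WT pair it called 4. The log2 fold changes in those fits were 4.22, 4.08 and 4.22 for Fos and 3.82, 3.54 and 3.82 for Egr1. Without the Het odor library, Het water is alone in its block and adds nothing to the odor effect. That fit thus repeats the one without the Het pair and is not a separate check. Both calls were lost too without the mean-variance trend (0.444 and 0.402), Fos with median-ratio scaling (0.0519) and Egr1 without genotype as a block (0.0684). Genes at least 2-fold higher in each of the 3 genotypes numbered 27, where 1.8 would be met if the genotypes were independent, and 14 were 2-fold lower in each (2.7 if independent). These expected numbers treat all genes as equally variable. Scarce or noisy genes pass 2-fold more readily in any pair, so the expected numbers are not chance levels. Besides those above, the 27 held Nr4a3, Egr2, Junb, Maff, Sik1, Zfp36 and Dusp5, all known to be induced by stimulation, and Pcdh10, an activity-dependent adhesion gene of olfactory neurons. The rest were Hspa1a, Ly6g, Cd40lg, Nfkbid, Sfn, Bcl6b, Gprc5a, Hs3st1, Akr1b8, Pilra, Mat1a, Irs2, Adra2c and the receptor Olfr206. By the naming rule, which leaves out receptors, the genes closest to a call among those lower after odor were Deb1 (-1.26 ± 0.19), Haus1 (-1.51 ± 0.26), Eef1e1 (-0.88 ± 0.16), Zfp955b (-0.89 ± 0.17) and Mnd1 (-1.37 ± 0.26), with adjusted p from 0.819 to 0.882, none passing.

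**Figure D2:**
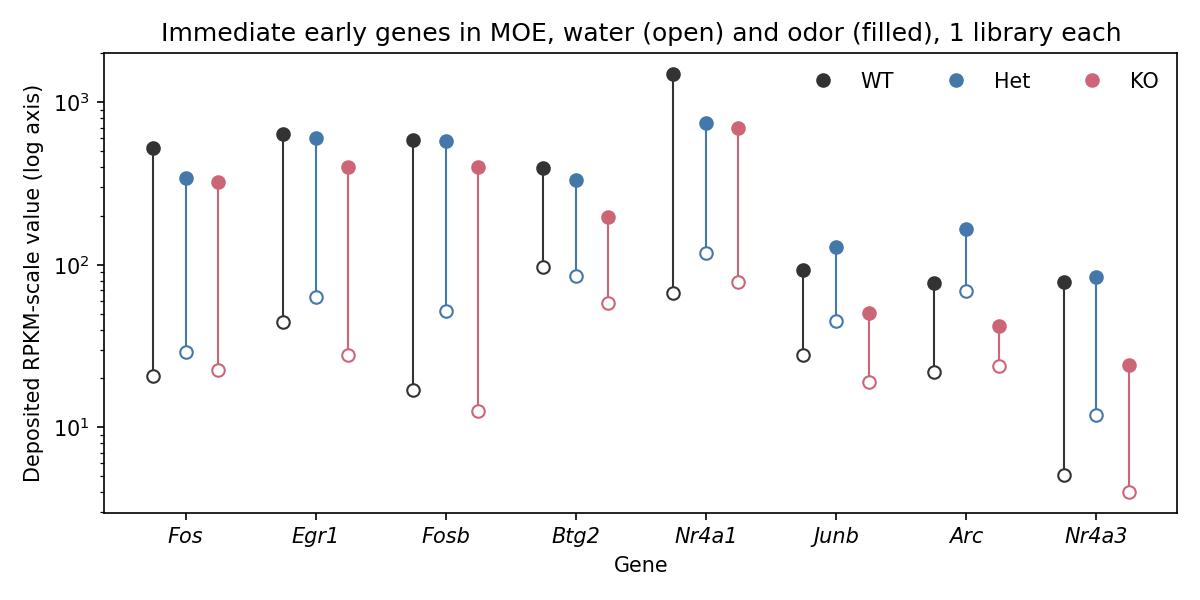
Deposited RPKM-scale value (vertical log axis) of 8 immediate early genes (horizontal axis) in MOE; open points are water, filled points are odor, colors are genotypes, and each point is 1 library. Fos went from 20.7 to 523 in WT, from 29.2 to 341 in Het and from 22.4 to 322 in KO, and every filled point lies above its open partner.

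With the preset correlation, 8 of the 29 lists differed between odor and water. The immediate early list was higher (adjusted p = 5.38e-34; adjusted p = 0.9 with an estimated correlation). Odorant receptors were lower, 431 of 579 with a median log2 of -0.42 (adjusted p = 1.26e-08; adjusted p = 0.932 with an estimated correlation), and this call was lost without the WT pair (median -0.09, adjusted p = 0.335), the Het pair (-0.12, 0.102) or the Het odor library (-0.12, 0.112), while without the KO pair the median was -0.96 (adjusted p = 1.43e-35). Nuclear-encoded genes of oxidative phosphorylation, the mitochondrial energy supply, were lower (69 of 87, median -0.20, adjusted p = 1.07e-07), as in Ndufa5 (-0.59 ± 0.17) and Atp5k (-0.66 ± 0.2). Marker lists were higher for microvillous cells (8 of 9, median 0.68, adjusted p = 0.00174) and for sustentacular cells, the glia-like support cells (15 of 16, median 0.25, adjusted p = 0.00724). Among microvillous markers Foxi1 (0.68 ± 0.15), Itpr3 (0.63 ± 0.17) and Ascl3 (0.97 ± 0.32) were higher. Chat, the 1 member that was lower, was at -1.4 ± 0.43 and fell in each genotype. Krt8 of sustentacular cells was at 0.74 ± 0.2. Heat shock genes (11 of 12, median 0.24, adjusted p = 0.00281), axon guidance genes (18 of 28, median 0.17, adjusted p = 0.0185; Sema7a 0.92 ± 0.18) and other-lineage transcription factors (17 of 24, median 0.13, adjusted p = 0.022) were also higher. For these 6 lists the adjusted p was 0.9 to 0.932 with an estimated correlation. Without the WT pair the calls of sustentacular (median 0.17, adjusted p = 0.392), heat shock (0.10, adjusted p = 0.223) and transcription factor genes (0.17, adjusted p = 0.161) were lost, and the microvillous median was 0.45 and that of axon guidance 0.27. Without the KO pair the axon guidance call was lost (0.07, adjusted p = 0.341), and the medians were 0.43 for sustentacular, 0.61 for heat shock, 0.20 for transcription factor and -0.09 for oxidative phosphorylation genes. The transcription factor call was lost as well without the Het pair (0.07, adjusted p = 0.0598) or the Het odor library (0.07, adjusted p = 0.0569) and with a minimum of 100 reads (adjusted p = 0.119), and the heat shock median was 0.14 without the Het pair or the Het odor library. For these lists too, leaving out the Het odor library repeats leaving out the Het pair and is not a separate check. With quantile normalization the sustentacular median was 0.14. Of the single members named here after the immediate early genes, none passed over all genes (adjusted p = 0.882). Fry called 1 list, the other-lineage transcription factors (adjusted p = 0.0214).

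Olfr2, a receptor for octanal, was 71.5 with water and 22.1 with odor in WT, 10.4 and 14.3 in Het, and 57.0 and 62.0 in KO (log2 -0.37 ± 0.44, adjusted p = 0.909). Its pooled mOSN values were 83.7 in WT, 249.5 in Het and 102 in KO. Olfr160 was not listed in either table.

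The comparison of KO with WT asks what the loss of Dnmt3a changes in the whole epithelium. Apart from receptors, the gene nearest to a call upward was Avp (1.7 ± 0.2), the vasopressin gene, with 39.5 and 34.1 in WT, 58.1 and 55.5 in Het, and 121 and 121 in KO. After it came Iigp1, an interferon-induced GTPase, with 2.51 and 2.27 in WT, 3.54 and 2.46 in Het, and 32.6 and 14.8 in KO (2.96 ± 0.46), Ccl5 (2.72 ± 0.46), a T cell chemokine, Zbp1 (3.09 ± 0.61), a nucleic acid sensor, and Gbp10 (2.12 ± 0.42). Downward they were Tmem132b under both of its identifiers (-2.38 ± 0.36 and -1.74 ± 0.38), Agt, the angiotensinogen gene (-1.24 ± 0.25), Lrrc27 (-1.07 ± 0.22) and Btg2 (-0.86 ± 0.18). None passed: limma called 0 genes (185 higher and 141 lower at an unadjusted p under 0.05, smallest adjusted p = 1), and voom called 0.

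Of the gene lists, 10 differed between KO and WT with the preset correlation and 0 with an estimated one. Ribosomal protein genes were higher (64 of 73, median 0.22, adjusted p = 1.14e-09; adjusted p = 0.917 with an estimated correlation). Heat shock genes were lower, all 12 with a median of -0.63 (adjusted p = 2.66e-09), and immediate early genes were lower, 27 of 31 with a median of -0.35 (adjusted p = 2.22e-07), both with adjusted p = 0.917 with an estimated correlation. Odorant receptors were higher (385 of 579, median 0.38, adjusted p = 5.62e-07; adjusted p = 0.924 with an estimated correlation). Split by treatment, the KO over WT median was 0.04 with water and -1.24 with odor for heat shock genes, -0.03 and -0.56 for immediate early genes, and -0.48 and 1.27 for odorant receptors, whose median over both was 0.86 with a minimum of 100 reads. Trace amine-associated receptors (9 of 11, median 0.55, adjusted p = 0.00161) and microvillous markers (6 of 9, median 0.19, adjusted p = 0.0463) were higher as well, but turned between treatments, with -0.33 with water and 1.26 with odor for the former and 0.45 and -0.13 for the latter. Markers of immature neurons (16 of 20, median -0.25, adjusted p = 0.00107), ensheathing cells (9 of 11, median -0.19, adjusted p = 0.0185) and dividing progenitors (16 of 18, median -0.17, adjusted p = 0.0312) were lower, as were clustered protocadherins (18 of 24, median -0.20, adjusted p = 0.0131). For these 6 lists the adjusted p was 0.917 to 0.924 with an estimated correlation. Progenitors had -0.03 with water and -0.31 with odor, ensheathing cells -0.33 and -0.04, immature neurons -0.25 and -0.22, protocadherins -0.19 and -0.27, and ribosomal proteins 0.29 and 0.11. The microvillous call was lost with median-ratio scaling (adjusted p = 0.0537), with a median of 0.48 at a minimum of 100 reads, and the ensheathing call with a minimum of 100 reads (0.101). Mature neuron markers did not differ by this test (17 higher, 5 lower, median 0.12, adjusted p = 0.18), but turned between treatments as the receptors did, with -0.22 with water and 0.38 with odor. Among all list members 1, Taar5, passed adjusted over the list alone.

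The odor experiment also asks whether induction differs without Dnmt3a. Odorant receptors lay lower after odor in WT (median log2 -1.03) and Het (-0.92, or -0.59 with a minimum of 100 reads) and higher in KO (0.74); 519 of 579 had a more positive odor effect in KO, with a median difference of 1.65, and 142 passed adjusted over the list alone. Olfr1216 went from 54.9 to 16.8 in WT, from 37.8 to 11.1 in Het and from 35.3 to 207 in KO. Heat shock genes went the other way: Hspa1a, an inducible chaperone, went from 69.5 to 8255 in WT and from 327 to 4808 in Het, but from 123 to 255 in KO. All 12 heat shock genes had a lower odor effect in KO (median difference -1.12), and 5 passed adjusted over the list alone. Immediate early genes had medians of 1.55 in WT, 1.26 in Het and 0.77 in KO, with 29, 29 and 27 of 31 higher. Atf3, a stress-induced transcription factor, went from 6.08 to 96.8, from 1.86 to 31.6 and from 11.2 to 14.4. Against the common effect in WT and Het, 24 of the 31 had a lower odor effect in KO and 7 a higher one. A small p for odor favors members whose odor effect was alike between genotypes, so such members do not stand for the list. Among those with the smallest p for odor, Egr1 (3.82, 3.26 and 3.82), Fos (4.63, 3.52 and 3.81) and Fosb (5.07, 3.46 and 4.94) rose more in KO than in Het. Btg2 (2.01, 1.95 and 1.76) rose less.

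Limma called 0 genes for this difference (548 higher and 491 lower at an unadjusted p under 0.05, smallest adjusted p = 0.232), and voom called 0. By the naming rule, which leaves out receptors, the genes closest to a call all had adjusted p = 0.232. Upward they were Mup18 (2.88 ± 0.33) and Mup17 (3.57 ± 0.43), which encode major urinary proteins, BC100530 (4.6 ± 0.64), Snhg11 (3.21 ± 0.45) and Ifitm6 (3.27 ± 0.46). Downward they were Prg2 (-3.76 ± 0.39), an eosinophil granule protein, Ppbp (-3.74 ± 0.4), a platelet chemokine, Tlcd2 (-4.89 ± 0.54), Dspp (-7.14 ± 0.8), a dentin protein, and Ifitm5 (-2.93 ± 0.33), a bone protein. With the preset correlation 15 lists differed, with odorant receptors at adjusted p = 1.78e-45 (adjusted p = 0.598 with an estimated correlation). Heat shock genes (adjusted p = 1.2e-09) and immediate early genes (24 of 31 lower, median -0.50, adjusted p = 0.00332) had an adjusted p = 0.716 with an estimated correlation.

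Markers of other cells moved with the same library pairs. The odor effect was higher in KO for mature neuron markers (20 of 22, median 0.60, adjusted p = 5.96e-06), trace amine-associated receptors (all 11, median 1.03, adjusted p = 0.000321), axon guidance genes (23 of 28, median 0.23, adjusted p = 0.0106) and Y-linked genes (all 4, median 1.02, adjusted p = 0.00593). It was lower for replication-dependent histones (57 of 64, median -0.85, adjusted p = 3.29e-15), oxidative phosphorylation (64 of 87, median -0.25, adjusted p = 0.000556), and markers of macrophages (13 of 14, median -0.63, adjusted p = 0.000334), horizontal basal cells (all 8, median -1.32, adjusted p = 0.0013) and sustentacular cells (14 of 16, median -0.56, adjusted p = 0.00332). Endothelial and mesenchymal markers (7 of 12 lower, median -0.06 and mean -0.67, adjusted p = 0.00505), Bowman gland markers (9 of 12, median -0.76, adjusted p = 0.00637) and dividing progenitors (13 of 18, median -0.39, adjusted p = 0.0204) were lower too. The latter 2 rest mostly on 1 of the other genotypes, with medians in WT, Het and KO of 1.00, 0.14 and 0.03 for Bowman gland and -0.10, 0.45 and -0.26 for progenitor markers, and histones had -0.02, 0.52 and -0.57. For each of these 12 lists the adjusted p was 0.716 with an estimated correlation. The median Y-linked value was 39.3 in Het odor and 69.7 to 96.8 in the other libraries. The labels do not give the sex of the animals. A different mix of sexes is thus not separated from odor in these genes, here or in other comparisons that use Het odor. The sustentacular call was lost with quantile normalization (median -0.33, adjusted p = 0.0714) and the progenitor call with a minimum of 100 reads (0.106). Of the endothelial and mesenchymal list, 4 members passed downward adjusted over the list alone; Col1a1, a collagen, was 2223 and 3778 in WT, 2615 and 4931 in Het, and 3596 and 746 in KO (-3.11 ± 0.42, adjusted p = 0.232).

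Genes with a mean value of at least 1 over the 6 libraries, chosen by their odor effect in 1 genotype, were then compared in the 2 others. The 756 such genes at least 2-fold higher after odor in WT had a median log2 of 0.16 in Het and -0.05 in KO, and the 1028 that were 2-fold lower in WT had -0.08 in Het and 0.58 in KO. The 780 genes higher in KO had -0.73 in WT and -0.05 in Het, and the 595 lower in KO had 0.07 and 0.11. The 619 higher in Het had 0.12 in WT and 0.09 in KO, and the 915 lower in Het had -0.30 and 0.16. No test applied to these medians, since each genotype had 1 pair of libraries.

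**Figure D3:**
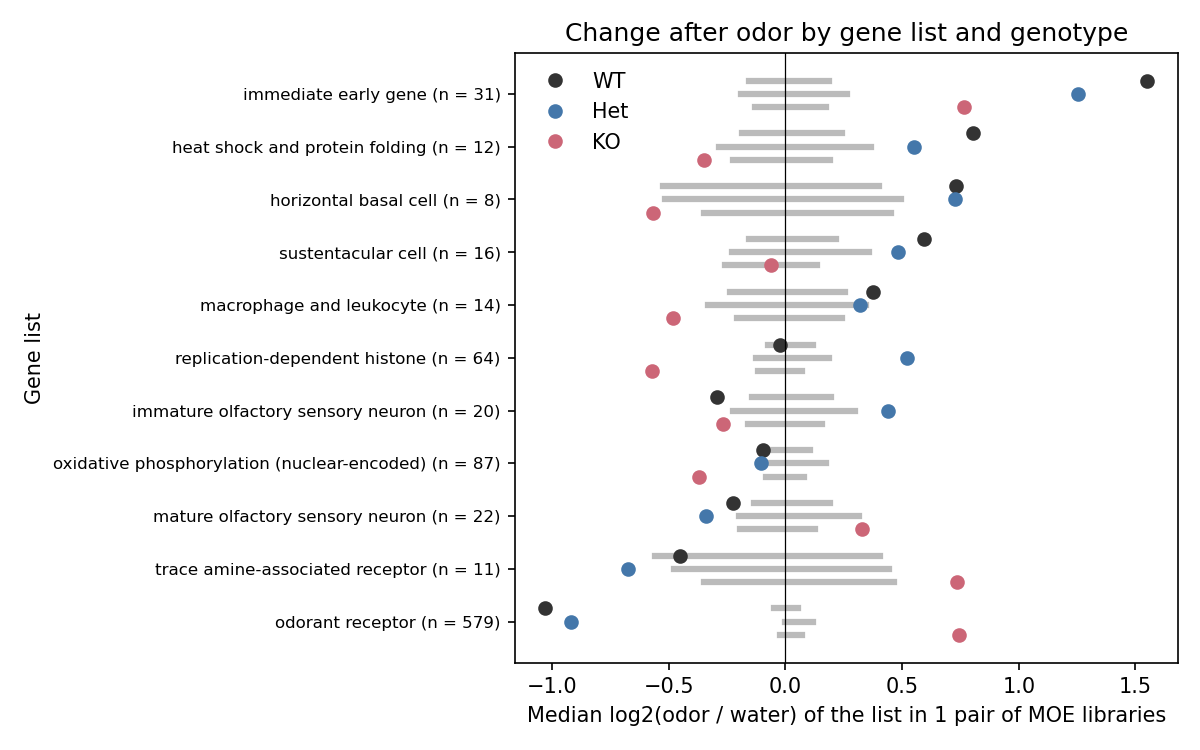
Median log2 ratio of odor to water (horizontal axis) for 11 gene lists (vertical axis, with the number of genes) in 1 pair of MOE libraries per genotype; points are the medians and grey bars the central 95% of 10000 random lists matched on expression. Odorant receptors lie at -1.03 in WT, -0.92 in Het and 0.74 in KO, and immediate early genes at 1.55, 1.26 and 0.77.

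Of the 6 libraries, Het odor stood apart. On the first principal component (38.0% of the variance) it lay at 68.6 and Het water at 19.7, and the other 4 between -35.9 and -13.9. Across genes, Het water had a Pearson correlation of 0.958 with WT water, 0.954 with KO water and 0.952 with Het odor, which lay at 0.909 to 0.928 with the other 4. The most alike were WT odor and KO water (0.967), and WT water was closer to KO odor (0.956) than to WT odor (0.940). On the second component (24.7%) WT went from -39.6 with water to 47.0 with odor and KO from 21.2 to -17.8, and marker lists above turned as well. Among genes with a mean of at least 10 in the higher libraries, both Het libraries were at least 2-fold above all 4 others in 26 and below them in 37, of which 28 were receptors, against 1 and 2 genes for WT and 9 and 4 for KO. Genes above included Tet3, the chitinase-like Chi3l4 (680.3 and 1031 in Het, 156 and 46.1 in WT, 39.5 and 23 in KO) and Thy1, a neuronal surface protein (142 and 130.5 in Het, 43.3 and 39.2 in WT, 26.4 and 30.4 in KO). Mobp, Hapln4 and Tuba8 were among them as well. Cnga4, a subunit of the olfactory cyclic nucleotide-gated channel, was 555 and 369 in Het against 1889 and 1115 in WT and 1061 and 1170.3 in KO.

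In Het against WT, markers of mature neurons were lower (21 of 22, median -1.05, adjusted p = 8.32e-19; 20 passed adjusted over the list alone), and so were odorant receptors (504 of 579, median -0.89, adjusted p = 2.2e-22), each with adjusted p = 0.561 with an estimated correlation. Olfactory activity-linked genes were lower (12 of 13, median -0.79, adjusted p = 1.19e-07), with S100a5, a calcium-binding protein of these neurons, at -1.92 ± 0.38. Also lower were trace amine-associated receptors (10 of 11, median -0.90, adjusted p = 0.000314), axon guidance genes (20 of 28, median -0.34, adjusted p = 6.81e-05), clustered protocadherins (19 of 24, median -0.35, adjusted p = 0.00104) and Y-linked genes (all 4, median -0.69, adjusted p = 0.00793). Higher were markers of dividing progenitors (all 18, median 0.41, adjusted p = 0.000165; Neurog1 1.56 ± 0.4), macrophages (13 of 14, median 0.62, adjusted p = 0.000746; C1qc 1.67 ± 0.3) and microvillous cells (all 9, median 0.37, adjusted p = 0.0258), histones (60 of 64, median 0.52, adjusted p = 6.15e-10), ribosomal proteins (69 of 73, median 0.28, adjusted p = 3.01e-09) and oxidative phosphorylation (69 of 87, median 0.23, adjusted p = 8.11e-05). For these 11 lists the adjusted p was 0.561 or 0.562 with an estimated correlation. Without the Het odor library the calls of progenitors (median 0.07, adjusted p = 0.247), protocadherins (-0.22, 0.117), histones (0.13, 0.14) and Y-linked genes (-0.18, 0.336) were lost, and the medians were -0.55 for odorant receptors, 0.20 for macrophages and 0.12 for oxidative phosphorylation. With a minimum of 100 reads the calls of microvillous markers (0.36, adjusted p = 0.0575) and protocadherins (-0.14, 0.09) were lost.

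No single gene passed in either Het comparison. Limma called 0 genes for Het against WT (395 higher and 582 lower at an unadjusted p under 0.05, smallest adjusted p = 0.706; voom 0), and 0 for KO against Het (800 higher and 587 lower, smallest adjusted p = 0.445; voom 0). Apart from receptors, which the naming rule leaves out, the genes nearest to a call in Het against WT were Ier5l (1.56 ± 0.19), Mnd1 (2.71 ± 0.32), Tet3, Thy1 (1.71 ± 0.22) and Bex1 (1.37 ± 0.21) upward, and the potassium channels Kcng1 (-1.48 ± 0.2) and Kcnc4 (-1.31 ± 0.22), Coro2a (-1.26 ± 0.19), Aard (-2.53 ± 0.39) and Cnga4 (-1.68 ± 0.27) downward. In KO against Het, again apart from receptors, they were Lpcat4 (1.43 ± 0.18), Kcng1 (1.51 ± 0.2), Macrod1 (1.12 ± 0.18), Coro2a (1.22 ± 0.19) and Cd40lg (2.2 ± 0.36) upward, and Thy1 (-2.24 ± 0.22), Chi3l4 (-4.77 ± 0.52), Tet3 (-2.97 ± 0.34), Tuba8 (-4.25 ± 0.61) and Ier5l (-1.22 ± 0.19) downward.

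In KO against Het, 14 lists differed with the preset correlation, each with adjusted p = 0.619 with an estimated correlation. Odorant receptors (508 of 579, median 1.26, adjusted p = 6.84e-32) and mature neuron markers (all 22, median 1.21, adjusted p = 2.27e-19) were higher in KO, with 35 and 19 genes passing adjusted over the list alone. Also higher were activity-linked genes (12 of 13, median 0.79), trace amine-associated receptors (10 of 11, median 1.63), axon guidance genes (20 of 28, median 0.28) and Y-linked genes (all 4, median 0.63). Lower were histones (59 of 64, median -0.67), dividing progenitors (all 18, median -0.62), immature neurons (18 of 20, median -0.56), immediate early genes (26 of 31, median -0.53; 6 passed adjusted over the list alone, and Arc, a synaptic activity gene, was at -1.74 ± 0.3), oxidative phosphorylation (72 of 87, median -0.23), heat shock (11 of 12, median -0.61), ensheathing cells (9 of 11, median -0.47) and macrophages (10 of 14, median -0.71). The adjusted p of these 12 lists ranged from 2.35e-12 to 0.0168, and without the Het odor library immature neurons (median -0.12, adjusted p = 0.208), macrophages (-0.24, 0.0646) and Y-linked genes (0.22, 0.525) no longer passed, while histones had a median of -0.22, progenitors -0.28 and ensheathing cells -0.26.

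The mOSN table asks what Dnmt3a loss changes in the neurons themselves; its values are the authors' pooled values, with no error, replicate number or test. Mature neuron genes were lower in KO: 21 of 22 lay below WT with a median log2 of -0.64 (-0.25 after quantile normalization). The most abundant members were at -0.44 (S100a5), -0.40 (Stoml3), -0.27 (Gng13) and -1.13 (Omp, the olfactory marker protein). Omp was 16660.5 in WT, 10449 in Het and 7612 in KO, and Adcy3, the olfactory adenylyl cyclase, was 744, 664 and 434. All genes in the highest of 10 equal expression groups had a median of -0.40. Among random lists of like expression the median of the mature neuron genes was at percentile 0. Genes scarcely expressed in WT were mostly higher in KO. The mOSN values held no 0, and the lowest was 0.13 in WT, 0.06 in Het and 0.61 in KO. How far a filter on 0 values shaped the low genes is not known. Keratins of horizontal basal cells, the stem cells of the epithelium, went from 2.88 in WT to 8.38 in Het and 24.9 in KO for Krt5 and from 1.75 to 4.6 and 22.6 for Krt14, and all 7 members were higher in KO (median 2.45, percentile 100; 1.42 with a pseudocount of 5). Other-lineage developmental transcription factors were higher in 48 of 50 (median 1.40, percentile 100; 0.70 after quantile normalization and 0.77 with a pseudocount of 5) and Hox genes in 24 of 25 (median 1.14, percentile 89.43; 0.27 and 0.72). Hoxb13, for example, was 4.36, 11.3 and 17.6. The random lists were matched on expression and not on gene length, while the rise of low genes in KO was larger in short genes (below). The percentiles in mOSN thus do not separate a list's change from that of its gene lengths.

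At least 2-fold apart were 2579 genes higher and 419 lower in KO than in WT, 1556 and 298 against Het, and 1016 and 368 in Het against WT. Het lay between WT and KO in 1991 of the 2579 and in 327 of the 419. These genes were chosen for the distance between KO and WT, into which a Het value can readily fall, and no expected share was computed. The Het libraries were 1 of ScriptSeq and 1 of NuGEN, so Het values in between could also come from the kit. The counts therefore cannot show a graded effect of Dnmt3a dose. The excess of higher genes depended on scaling and pseudocount: 86.0% of the genes apart were higher in KO, 56.2% after quantile normalization (1006 and 784) and 91.2% with median-ratio scaling (2931 and 284), and a pseudocount of 5 left 920 higher and 288 lower. Median-ratio scaling moved the median of all genes from -0.13 to 0.00. Both WT libraries were made with ScriptSeq and both KO libraries with NuGEN, so kit and genotype cannot be told apart in these values.

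By the naming rule, the largest differences upward were Mid1, a ubiquitin ligase (6.0 in WT, 27.4 in Het, 60.2 in KO), Gpd1 (8.8, 12.2, 66.2), S100a11 (11.9, 31.2, 62.3) and Ugt2a1, an olfactory glucuronosyltransferase (175.3, 428.9, 780.3). After them came Rin1, Nrtn, Gadd45b, Krt8, Csf2ra, Hist1h2ak, Reep4 and Pglyrp1, which were 4.0-fold to 2.7-fold higher. Downward they were the Y-linked Kdm5d (70.3, 45.0, 3.6) and Ddx3y (148.3, 96.3, 16.3), the hemoglobin gene Hba-a2 (833.6, 205.0, 113.1), Tpm3-rs7 (62.2, 14.3, 13.8) and Ankrd26 (54.4, 12.5, 12.4). Inpp1, Dydc2, Psmb5, Dnmt3a, Lrrc23, Eif2s3y and Atp6v0b followed, 3.5-fold to 2.9-fold lower. All 4 Y-linked genes were lower in KO (median -2.76) and in Het (median -0.64) than in WT; the labels do not give the sex of the animals, so a different mix of sexes is not separated from genotype in these genes.

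Groups of genes abundant in these neurons had negative medians in KO mOSN against WT, and quantile normalization shrank or turned most of them. Odorant receptors had a median log2 of -0.35 (282 higher, 534 lower, percentile 0; -0.13 after quantile normalization) and were, of the groups in this paragraph, the one outside the central 95% of random lists on the low side. Activity-linked genes had -0.43 (10 of 13 lower), heat shock genes -0.45 (9 of 11), synaptic vesicle genes -0.36 (17 of 22), axon guidance genes -0.24 (19 of 27) and clustered protocadherins -0.23 (19 of 24); after quantile normalization these 5 medians lay between -0.12 and -0.02. Oxidative phosphorylation had -0.39 (69 of 87 lower), which went to 0.00 after quantile normalization, while Polycomb genes (-0.32, 17 of 22 lower) turned to 0.04 and DNA methylation genes (-0.16, 11 of 16 lower) to 0.05. Immediate early genes had a median of 0.29 (21 of 32 higher, percentile 100), while an abundant member such as Fos had 641 in WT, 614 in Het and 499 in KO.

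Markers of other cells had positive medians in KO mOSN against WT. They lay above the central 95% of random lists for sustentacular cells (0.36, 10 of 16 higher), Bowman gland (0.93, 5 of 8) and erythroid cells (0.53, 5 of 8), at percentiles 99.91, 98.24 and 98.98; the Bowman gland median was 0.26 after quantile normalization. They lay within it for microvillous cells (0.68, 6 of 7), ensheathing cells (0.56, 7 of 9) and macrophages (0.91, 9 of 10), which went to 0.09, 0.01 and 0.26 after quantile normalization, and for dividing progenitors (0.72, 11 of 14) and endothelial and mesenchymal cells (0.72, all 9), which turned to -0.10 and -0.08 after quantile normalization. The most abundant members diverged: Cyp2g1 and Sec14l3 of sustentacular cells were 132 and 134 in WT and 80.9 and 46.7 in KO, while Ugt2a1 was higher. Germline genes (0.40, 15 of 19 higher; 0.10 after quantile normalization), imprinted genes (0.60, 16 of 24; 0.08) and trace amine-associated receptors (0.20, 6 of 9, percentile 99.01; 0.38) had positive medians, and vomeronasal receptors had 0.49 (7 of 10, percentile 1.5), which turned to -0.60 after quantile normalization. Immature neuron markers (-0.01), ribosomal proteins (-0.03) and histones (-0.10) turned positive with median-ratio scaling (0.13, 0.11 and 0.04) and with quantile normalization (0.34, 0.30 and 0.14).

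The change in mOSN followed expression level. With genes ranked by expression into 10 equal groups, the median log2 of KO over WT was 1.05 in the lowest group, 1.11 in the next, 0.08 in group 4 and -0.40 in the highest. Het over WT gave 0.28 in the lowest and -0.05 in the highest. In MOE the KO medians stayed between -0.03 and 0.02. The slope of log2 KO on log2 WT was 0.764 in mOSN and 0.983 in MOE, and that of Het 0.917 and 0.951. Across 13356 genes the KO effects in mOSN and in MOE had a Pearson correlation of -0.033 and a Spearman correlation of -0.012, and 51.3% had the same sign. These are correlations across genes, which are not independent replicates.

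**Figure D4:**
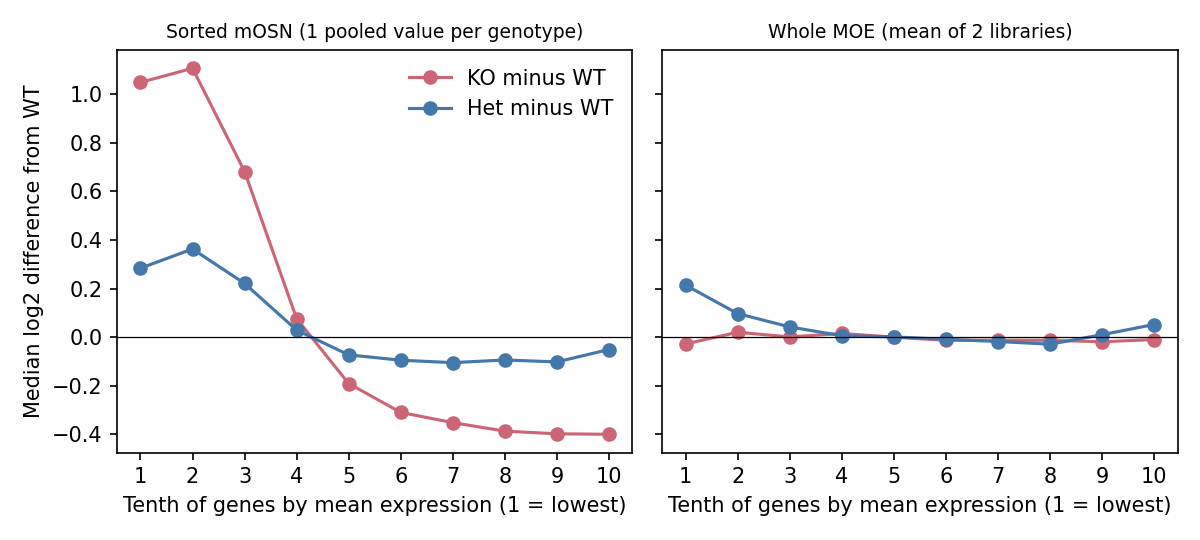
Median log2 difference from WT (vertical axes) in 10 groups of genes ranked on mean expression (horizontal axes, 1 is the lowest) in pooled mOSN values and in MOE means of 2 libraries; points are medians of about 1474 and 1460 genes. In mOSN, KO minus WT runs from 1.05 in the lowest group to -0.40 in the highest, and in MOE it stays between -0.03 and 0.02.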

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

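Of the tests in this part, those of the share of mature neurons and of scaling were chosen after the result was seen, and that of gene length before it. The results below differed in their response to odor between KO and the other genotypes by camera with the preset correlation on the interaction, and none did with an estimated correlation (adjusted p = 0.598 for odorant receptors and 0.716 for the others). Each value is the list's median log2 odor effect in KO against the common effect in WT and Het, followed by the medians in WT, Het and KO. Mature neuron markers were at 0.598 (-0.224, -0.342 and 0.33). Horizontal basal cell markers were at -1.321 (0.73, 0.726 and -0.569). Sustentacular cell markers were at -0.556 (0.593, 0.482 and -0.064). Macrophage and leukocyte markers were at -0.627 (0.374, 0.321 and -0.481). Endothelial and mesenchymal markers were at -0.06, with a mean of -0.671 (0.095, 0.465 and -0.18). Odorant receptors were at 1.651 (-1.029, -0.919 and 0.742), and trace amine-associated receptors at 1.035 (-0.454, -0.674 and 0.736). Heat shock genes were at -1.124 (0.803, 0.549 and -0.348). Y-linked genes were at 1.023 (-0.314, -0.96 and 0.269), where the sex of the animals, which the labels do not give, is not separated from odor.

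The pattern weighed here is that of the odorant receptors, lower after odor in WT and Het and higher in KO. Gene length as the cause is argued against by non-receptor genes matched on length and expression, whose medians were 0.107, -0.061 and -0.093 where the 448 matched receptors were at -1.045, -0.913 and 0.759. A shift in scaling would move receptors and those matched genes alike, and is argued against as the cause of the gap between them, which was -1.152, -0.852 and 0.852; which of the groups moved in absolute amount cannot be read from these scaled values. A different share of mature neurons falls short as the whole cause in WT, where their markers were at -0.224 (quartiles -0.469 and -0.002) against -1.029 for receptors. In Het the markers were at -0.342 (quartiles -0.574 and -0.101) against -0.919. In KO they were at 0.33 (quartiles 0.147 and 0.541) against 0.742. The gap was smaller in Het and KO, where the markers do not decide how much of the receptor change such a share makes. Differences between libraries unrelated to odor, with 1 library per genotype and treatment, and a response to odor that depends on Dnmt3a both stay open; receptors were not alone in turning, as the lists above show and as on the second principal component over all genes WT went from -39.6 with water to 47.0 with odor and KO from 21.2 to -17.8.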

How the results depend on the processing

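The estimated correlation and fry for the lists, scaling (for MOE lists median-ratio alone), the trend, the threshold of 0.10, blocks, leaving out a genotype's pair for gene counts, the fold limits and the treatment splits were fixed before the data were examined; the pseudocount of 5, the minimum of 100 reads, voom, the Het odor library or both Het libraries left out, and quantile normalization and leaving out a pair for the MOE lists were chosen after. Odor against water gave 2 genes, and 1 with median-ratio scaling, 1 without genotype as a block, 0 without the mean-variance trend, 4 with a threshold of 0.10, 4 with at least 100 reads, 6 with voom, 0 without the Het odor library, and 0 to 4 in the leave-one-out fits. For lists, camera with an estimated correlation called 0 in each of the 5 comparisons, against 8 (odor), 10 (KO against WT), 14 (KO against Het), 13 (Het against WT) and 15 (interaction), and fry called 1 for odor and 0 for the other 4; by construction both rest on 2 or 1 residual degrees of freedom. Leaving out a pair gave 5 to 17 lists for odor. For odor, leaving out the Het odor library gives the same effect as leaving out the Het pair. In mOSN the 2998 genes apart between KO and WT became 1790 with quantile normalization and 1208 with a pseudocount of 5, which by construction damps low values and gave 648 against 1854 between KO and Het and 405 against 1384 between Het and WT. List medians of KO over WT turned with median-ratio scaling and with quantile normalization for immature neurons (-0.009 to 0.13 and 0.335), ribosomal proteins (-0.031 to 0.107 and 0.305) and histones (-0.096 to 0.042 and 0.136), and with quantile normalization for vomeronasal receptors (0.489 to -0.601). The Dnmt3a odor effect of 0.088 turned to -0.023 with voom and -0.068 without the Het odor library, ranging from -0.068 to 0.239 in the leave-one-out fits, and its KO against Het difference of -0.15 turned to 0.084 without the Het odor library; neither had passed. With a limit of 1.5-fold, genes higher in WT had a median of 0.011 in KO (-0.054 at 2-fold) and genes higher in KO -0.263 in WT (-0.732). With a log2 limit of 2, the latter had -1.074, genes lower in WT 1.015 in KO (0.578), genes higher in Het -0.032 in WT (0.117) and genes lower in Het 0.537 in KO (0.16). The correlation of KO effects, -0.033, was -0.045 for values of at least 5, -0.018 with water and -0.022 with odor. Except where the construction is given, the cause was not tested. Of the remaining values over all alternatives, 473 for lists, 622 for named genes and 106 others kept direction and side of the threshold or, without a test, moved by less than the spread used for them; among the latter the DNA methylation list in mOSN turned from -0.159 to 0.05 with quantile normalization. No paired analysis was possible because, for pairing by replicate number, the mOSN libraries were deposited as 1 pooled value per genotype and MOE had 1 library per genotype and treatment; the genotype block of the odor test joins libraries of a genotype, not known animals. For the same reason the alternatives fixed for mOSN with a kit term, a replicate block, 1 kit alone, leave-one-out fits, no trend or another threshold, and the correlation with the kit difference, were not run. A median of 222 to 396 reads per gene limits scarce genes, of which 456 to 754 per MOE library had under 10 reads; mOSN depth is unknown.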

Other observations

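Of the tests in this part, those on Tet3, those of other epithelial cells and of a constant amount in mOSN were chosen after the result was seen; the kit difference and the splits of the libraries were fixed before. Several gene groups had no call in any of the 5 MOE comparisons with the preset correlation. For odor against water, the erythroid list had a median log2 of -0.04 and a mean of 0.05 (adjusted p = 0.852). Its hemoglobin gene Hbb-b1 went from 27975 to 20539 in WT, from 21471 to 38261 in Het and from 30044 to 16299 in KO. Vomeronasal receptors had -0.29 (8 of 9 lower, adjusted p = 0.187), germline genes -0.20 (7 of 8 lower, adjusted p = 0.13), imprinted genes -0.04 (12 of 22 lower, adjusted p = 0.766), Polycomb genes -0.08 (15 of 22 lower, adjusted p = 0.693) and synaptic vesicle genes 0.02 with a mean of -0.01 (adjusted p = 0.766). DNA methylation genes had a median of -0.06 and a mean of 0.06 (adjusted p = 0.693), where Gadd45b, a stress and activity gene linked to demethylation, was 27 and 45.9 in WT, 58.1 and 108 in Het and 38.2 and 47.9 in KO. In Het against WT mOSN, without a test, Hox genes had a median of 0.72 (0.41 with quantile normalization, 0.49 with pseudocount 5), other-lineage transcription factors 0.69 (0.33 and 0.40), horizontal basal cell markers 0.76 (0.41 and 0.30) and mature neuron markers -0.09 (-0.06 and -0.09).

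Single genes of other groups differed widely between libraries. Lcn3, a secreted lipocalin of the nasal glands, was 820.1 with water and 11722 with odor in WT, 1337 and 1010.2 in Het, and 3449 and 3562 in KO. Dnajb1 and Hspb1, heat shock genes, were 640.4 and 432 in WT with odor, 316 and 273 in Het with odor, and at most 73.3 and 66.7 in the other 4 libraries. Foxd3, a neural crest factor of ensheathing glia, was 15.6 and 6.64 in WT, 4.71 and 5.33 in Het, and 1.61 and 1.89 in KO (log2 -2.26 ± 0.53 against WT, adjusted p = 1), and Fabp7, a glial fatty acid-binding protein, was 989 and 306, 429 and 205, and 283 and 264. For odor against water, the real split of the 6 MOE libraries gave 2 genes and the highest of the other splits 1, and 10 splits are too few for a share under 0.05. Of the other splits, 6 part a single genotype's pair, which with genotype as a block leaves the odor effect of that genotype. Taking the other library of a pair only turns the sign of that fit, so these 6 are 3 fits met 2 times each. The splits with 1 gene are among them, and the 3 that part all pairs gave 0. At an unadjusted p under 0.05 the real split gave 711 genes, and 5 of the 9 others gave more, 883 to 1295. The counts of 883 and 1295 are each 1 fit of a single genotype's odor effect, met 2 times. The 3 others that part all pairs gave 365, 580 and 1214, so by this count the real split did not stand out.

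In mOSN, values were spread less widely in KO than in WT, with low genes higher and abundant genes lower by their medians. No mOSN value was 0, so genes at 0 in a genotype may be missing. Whether such a filter narrowed the KO spread was not tested. A constant amount added to every KO value is argued against as the whole cause by the rise of low genes, 2.79 times as large in the shortest 20% of them as in the longest 20% (95% interval 2.49 to 3.09), although 0.0% of KO values lay below 25% of the median rise, which such an amount would also give; a constant number of reads per gene, which would raise short genes more (by up to their length ratio of 8.37), stays open, since choosing low genes by value limits the rise of short ones. RNA of the whole epithelium carried into the KO sort is argued against as well: the low genes' rise would need a median of 30.8% of whole KO MOE RNA (quartiles 10.4 to 84.0), while 19 abundant markers of other cells allow a median of 0.79% (quartiles 0.54 to 2.05, highest 26.9 for Ugt2a1), of which 10 were lower in KO mOSN than in WT, as Sec14l3 (46.7 against 134), and 9 were higher, as Krt18 (138 against 71.4) and Ugt2a1 (780.3 against 175). The slope of KO on WT was 0.219 higher in MOE, made with 1 kit, than in mOSN, where kit and genotype are confounded, so the kit and the loss of Dnmt3a cannot be told apart. RNA of a single other cell type, such as horizontal basal cells, also stays open and may add to the higher keratins Krt5 and Krt14.

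Tet3 was higher in both Het MOE libraries than in the 4 of WT and KO. A lower dose of Dnmt3a is argued against by KO, where Tet3 was at -0.15 ± 0.34 (log2) against WT, and by Het mOSN, where it was 171 against 178 in WT. A larger share of a cell type with a marker list falls short, since the highest such median was 0.62, of the macrophage list, against 2.82 for Tet3. Reads shared with the related Tet1 are argued against by its -0.11 ± 0.27. An altered Tet3 allele or transgene in the Het animals and cells without a marker list could also raise it, and neither was tested.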
